A study of Mus musculus with 15 samples.

How the data were processed

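RNA was measured in sorted macrophages. The labels' protocols describe a sort of YFP-positive, F4/80-positive cells without setting the WT samples apart. They name mice with a Cre recombinase under the Csf1r promoter, a conditional BRAF V600E allele and a conditional YFP reporter. BRAF V600E is a mutant kinase that keeps the MAPK pathway active. YFP marks cells in which the recombinase acted, and F4/80 is a surface antigen of mouse macrophages. The groups are called VE (mutant) and WT after the source labels, which carry YFP+ for the VE samples and leave it out for the WT samples. At 6 months the titles also carry YFP for VE only. The WT cells may therefore not have been sorted on YFP. In that case the sort gate differs with genotype in every VE against WT comparison, and the 2 cannot be told apart. The samples came from liver and brain at 1 month and from brain at 6 months, and the series' design text gives the brain region as brain stem. Titles of the 6-month samples also carry the abbreviations sc and veh, which the labels do not explain; these samples are called brain here because their cell type label says so. The liver had 3 WT and 3 VE samples, the brain at 1 month 2 WT and 3 VE, and the brain at 6 months 2 WT and 2 VE. Nothing in the labels says that samples came from separate animals, so p-values measure the spread between these samples, which may be partly technical.

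RNA was amplified by 14 cycles of PCR with the SMART-seq V4 kit, 10 ng of the product went into libraries with another 8 cycles, and reads were paired ends of 50 bp, per the labels' protocols. STAR and the builds mm10 and GRCh38 are named, without versions or roles, per the submitters' processing notes. The quantification tool and the annotation are not given in the sources used here. The deposited values are length-scaled transcript abundances (TPM), summed by the authors per Ensembl gene, with separate tables for the ages and 39017 genes in each. Each of the 28 sample columns sums to 1000000, so TPM keeps no depth and the number of reads behind a value is unknown. No counting intervals or detection floors were therefore computed, and a TPM of 0 is given only as listed at 0. The kit does not mark strand, so overlapping and antisense genes cannot be told apart.

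Most samples had a pair of repeat columns, while liver WT 5 and the 6-month WT 1 sample had a single column. Repeat columns were averaged as TPM and counted as 1 replicate, a choice made after the tables had been seen. Columns of 1 sample had Spearman correlations across genes of 0.675 to 0.727 in brain VE at 1 month and 0.676 to 0.694 in brain WT, against 0.666 to 0.734 and 0.685 to 0.700 between samples of those groups. In liver the repeat columns had 0.819 to 0.857. At 6 months they had 0.786 to 0.825. No pair of columns was identical. Genes with at least 1 TPM numbered 10335 to 11054 in the brain libraries at 1 month, 11166 to 12061 in liver and 10391 to 12801 at 6 months. The low correlation in brain at 1 month goes with genes seen in some columns and missed in others, which widens the error of low and moderate values.

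Symbols and coordinates came from GENCODE M21 on GRCm38, which named 96.4% of the gene identifiers. Genes with at least 1 TPM in at least 2 libraries of a table were tested on log2(TPM + 1) with limma-trend (limma 3.58.1 in R 4.3.3, with the data.table package at version 1.17.8), 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change on this scale understates the change of low genes. The 4 groups of the 1-month table were fitted together, which gives them 1 estimate of the spread, and the 6-month table was fitted on its own. Array weights, which are lower for noisier libraries, were 0.363 to 0.504 in brain at 1 month and 1.24 to 2.79 in liver. An equal spread in both organs, which the joint fit assumes, therefore did not hold. The shared estimate is likely too small for brain, and p-values that involve brain at 1 month are likely too low. For liver the shared estimate is likely too large, and p-values of VE against WT in liver are likely too high. The tables were made separately, and levels were not compared between ages, except in a bound on the RNA of other cells at 6 months. The comparisons were VE against WT in each organ and age, brain against liver in WT, and the interaction of genotype and organ at 1 month.

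The 30 gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined, except where a choice is said to be later. Lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01. The same lists were tested with an estimated correlation and with fry, whose directional test asks whether the members move one way on balance and whose mixed test asks whether they change in either direction. The rule took Braf and Csf1r, then for each VE against WT comparison the 10 largest changes per direction past the threshold whose libraries do not overlap, with a mean of at least 5 TPM in the higher group. Predicted, noncoding and mitochondrial genes were left out of that ranking, as were sex-linked and receptor-segment genes. From each list it took up to 4 members, and for the other comparisons the 5 largest changes per direction. Some genes that this rule names are not reported here.

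Alternatives were other pseudocounts, filters, scalings and weights, fits of the compared groups alone, replicate and animal blocks, and leaving out each library. Added after seeing the data were other ways to combine repeat columns, a sex term, removal of the trend with transcript length and fits without single doubted columns. The code was tested on simulated data with 200 changed genes. For brain at 1 month it recovered 83.3% of genes changed by 4 on the log2 scale, 25.4% at 2 and 1.49% at 1, over 15123 genes. For liver over the same 15123 genes the shares were 89.4%, 41.8% and 5.97%. For 6 months over 12174 genes they were 100%, 56.7% and 8.96%. The simulation gave all libraries of a table the same normal spread for a gene and changed only genes of moderate or high level. It left out the larger spread of the brain libraries at 1 month and genes missed in single columns. The shares therefore test the code and may be too high for these data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.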

Results

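The data were 15 transcriptomes of sorted mouse macrophages, made to compare cells that express BRAF V600E after recombination in Csf1r-expressing progenitors with cells of WT mice. At 1 month there were 6 liver samples, 3 of each genotype, and 5 brain samples, 2 WT and 3 VE. At 6 months there were 4 brain samples, 2 of each genotype. Values are TPM from the deposited tables, and errors are SD over samples unless an SE of a log2 fold change is given. The TPM tables give no depth, so the precision of a value is known only from the spread between samples.

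The first comparison asked whether the cells carry the identity of their organ, in WT at 1 month. Brain cells expressed Gpr34, a purinergic-type receptor of microglia, at 9364 ± 69.9 TPM (SD, n = 2), against 0.115 ± 0.178 TPM in liver (SD, n = 3). Siglech, a sialic-acid-binding lectin of microglia, stood at 1868 ± 151 TPM in brain and 0.620 ± 0.230 in liver. Liver cells expressed Vsig4, a complement receptor of Kupffer cells, at 5733 ± 257 TPM, against 0.122 ± 0.0681 in brain, and Clec4f, a Kupffer cell lectin, at 2600 ± 402 TPM, against 0.0402 ± 0.0569. All 4 differences passed the threshold in limma, with log2 fold changes of brain over liver of 13.05 (SE 0.31) for Gpr34, 10.18 (SE 0.32) for Siglech, -12.32 (SE 0.25) for Vsig4 and -11.28 (SE 0.29) for Clec4f. Syngr1, Serpine2 and Fcrls were also higher in brain, with log2 fold changes from 8.97 to 9.23, and Apoc1, Cd5l and Id3 higher in liver, with values from -11.96 to -10.15.

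Of the homeostatic microglia list, 20 of 22 tested members were higher in brain and 0 lower, and 20 passed when adjusted over the list alone (camera adjusted p = 1.57e-23; adjusted p = 0.00883 with an estimated correlation). Of the Kupffer cell list, 19 of 20 were lower in brain and 1 higher, and the same counts held when adjusted over the list alone (camera adjusted p = 6.68e-28; adjusted p = 0.00159 with an estimated correlation). Of 21 type I interferon response genes, 17 were lower in brain than in liver, 17 also when adjusted over the list alone (adjusted p = 3.81e-14; adjusted p = 0.00403 with an estimated correlation). Hepatocyte markers were lower in brain for 12 of 14 tested members, and 14 were lower when adjusted over the list alone (adjusted p = 6.20e-15; adjusted p = 0.0157 with an estimated correlation). In all, 3097 of 15123 genes differed between the organs, 1758 higher and 1339 lower in brain, with a median log2 fold change over all genes of 0.21. With median-ratio scaling the split was 1188 higher and 1691 lower.

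In brain macrophages at 1 month the comparison asked what the mutant cells express at the earlier age. Ccl2, a chemokine that attracts monocytes, rose from 5.59 ± 2.21 TPM in WT (SD, n = 2) to 318 ± 230 TPM in VE (SD, n = 3), a log2 fold change of 5.31 (SE 0.66, adjusted p = 0.00307). Its neighbour Ccl12, another monocyte chemokine, rose from 290 ± 143 to 6624 ± 5654 TPM, by 4.22 on the log2 scale (SE 0.60, adjusted p = 0.00649). The cytokine Il6 rose from 19.9 ± 5.06 to 119.5 ± 35.0 TPM (log2 fold change 2.51, SE 0.44) and the related cytokine Osm from 0.133 ± 0.0885 to 6.62 ± 4.17 TPM (2.60, SE 0.46). The Il6 call was lost in 5 of 28 other settings, leaving out brain WT 4 among them, with log2 fold changes from 1.18 to 2.87. The Osm call was lost in 9, leaving out brain WT 5 among them, with 1.12 to 4.70. Each of these 4 genes was higher in 3 of 3 VE libraries than in both WT libraries. In the annotation, Ccl2 spans bases 82035571 to 82037453 and Ccl12 bases 82101845 to 82103400 of chromosome 11 (GRCm38), both on the forward strand.

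Across the 22 tested inflammatory cytokines and chemokines, these 4 rose, 0 fell and 18 did not pass; adjusted over the list alone, 7 were higher and 1 lower. The list was higher as a set in limma's camera test (adjusted p = 4.23e-05; adjusted p = 0.0551 with an estimated correlation). Of 21 type I interferon response genes, Ifitm3, a membrane protein that restricts viral entry, rose from 30.0 ± 10.1 to 247 ± 134 TPM, and the chaperone gene Rtp4 from 22.3 ± 2.57 to 80.1 ± 37.5 TPM. The Rtp4 call was lost in 15 of 28 other settings, among them leaving out any single liver library or either brain WT library. The other 19 did not pass, and 2 were higher when adjusted over the list alone. Ifit3 had 0.394, 30.6 and 40.5 TPM in the VE libraries and a mean of 0.00478 in WT. The interferon list was higher as a set (adjusted p = 0.00183; adjusted p = 0.13 with an estimated correlation). Cd52, a small surface glycoprotein of leukocytes, rose in 3 of 3 VE libraries from 465 ± 4.43 to 1498 ± 190 TPM, a log2 fold change of 1.68 (SE 0.19).

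Of 16 tested MAPK pathway target genes, the early response gene Ier3 rose from 0.0840 ± 0.0283 to 22.5 ± 11.5 TPM and 15 did not pass, while adjusted over the list alone 2 were higher. The second of these was the transcription factor gene Etv1, at 44.7 ± 13.8 TPM in VE and 8.25 ± 8.15 in WT (adjusted p = 0.0955 over all genes). The list passed in camera (adjusted p = 0.0361; adjusted p = 0.467 with an estimated correlation). Braf itself stood at 22.0 ± 17.7 TPM in VE and 24.1 ± 13.6 in WT, with a log2 fold change of -0.47 (SE 0.80). The tables do not separate the mutant from the normal allele. Csf1r, the receptor that macrophages need for survival, was at 808 ± 50.6 and 908 ± 70.8 TPM (-0.17, SE 0.16).

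Among the genes that fell were Fabp5, a fatty-acid-binding protein, from 27.0 ± 10.6 to 0.161 ± 0.0953 TPM, and Hmox1, the enzyme that degrades haem, from 44.5 ± 3.36 to 2.75 ± 3.15 TPM. Mobp, a myelin gene of oligodendrocytes, fell from 74.1 ± 36.8 to 1.28 ± 1.67 TPM. Other myelin genes were also lower in the VE libraries, without passing: Mbp at 28.6 ± 22.97 against 209 ± 67.8 TPM and Cnp at 6.21 ± 3.78 against 34.7 ± 19.5. Summed over the oligodendrocyte list, the VE libraries held 19.3, 56.7 and 49.3 TPM and the WT libraries 478.6 and 264 TPM. Of its 5 tested members 1 fell over all genes, and 1 was higher and 4 lower when adjusted over the list alone (camera adjusted p = 0.00530; adjusted p = 0.13 with an estimated correlation). F13a1, a coagulation factor gene of monocytes, fell from 9.79 ± 11.05 to 0.0270 ± 0.0310 TPM, a call kept in 5 of 25 other settings, with log2 fold changes from -5.60 to -0.08.

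The largest other changes were in genes of varied function, each low in one group. Pmm2, a mannose phosphate enzyme of glycosylation, had 36.2 ± 3.67 TPM in VE and 0.484 ± 0.0914 in WT. Etfrf1, a mitochondrial regulator, had 35.4 ± 7.24 and 1.21 ± 1.23, and Hscb, a cochaperone of iron-sulphur cluster assembly, 51.8 ± 20.3 and 2.15 ± 2.50. Kat8, a histone acetyltransferase, had 0.749 ± 1.14 in VE and 57.5 ± 13.7 in WT. The zinc finger gene Zfp78, the spindle gene Haus4 and Mymk had at most 0.193 TPM in any VE library and WT means of 36.6, 37.1 and 32.9 TPM. Ch25h, a cholesterol hydroxylase (139 ± 129 against 12.1 ± 16.9), Spp1, the matrix protein osteopontin (135 ± 92.5 against 17.7 ± 23.6), and H2-Ab1, of MHC class II (8.57 ± 14.6 against 85.8 ± 70.2), did not pass. Nor did Mertk, a receptor for dying cells, at 135 ± 52.3 and 208 ± 9.42 TPM.

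In all, 227 of 15123 genes passed between VE and WT brain cells, 72 higher and 155 lower. Leaving out 1 library gave 130 to 484. Fitted with limma without the liver groups, 0 genes passed the adjusted threshold and 830 had an unadjusted p under 0.05, against 2141 in the joint fit, and array weights left 22. In the joint fit the less noisy liver libraries lower the spread assumed for brain, so its brain p-values are likely too low. Of the 72 higher genes, 36 reached 1 TPM in each of the 6 VE columns, and of the 155 lower genes 47 did so in each of the 4 WT columns.

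**Figure D1:**
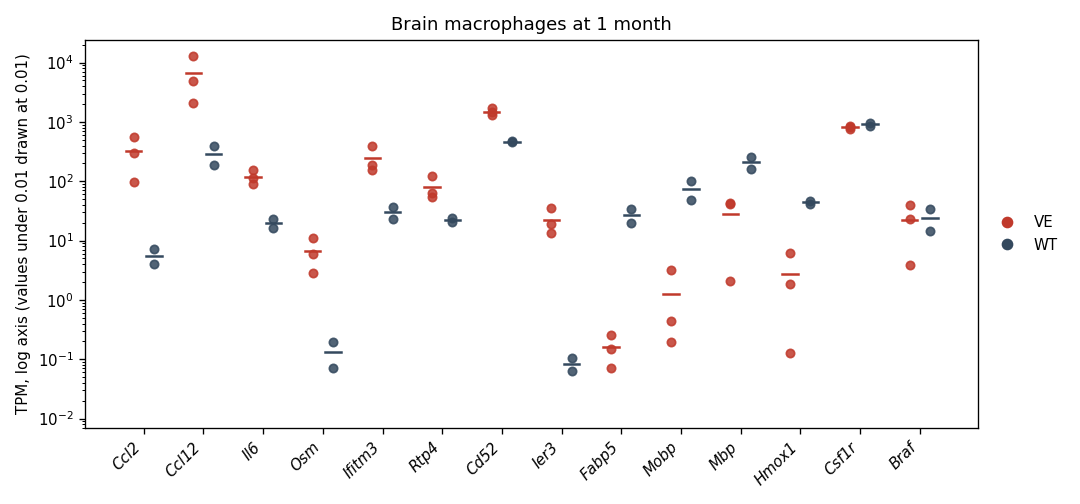
TPM of 14 genes (log axis) in brain macrophages at 1 month, with a point per sample, 3 VE and 2 WT, and bars at the group means. The 3 VE samples lie above both WT samples for Ccl2, Ccl12, Il6, Osm, Ifitm3, Rtp4, Cd52 and Ier3 and below both for Fabp5, Mobp, Mbp and Hmox1; Mbp, Csf1r and Braf did not pass the test.

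In liver macrophages at 1 month the same mutation was compared in another organ. Gpr34 rose from 0.115 ± 0.178 TPM in WT (SD, n = 3) to 20.6 ± 7.61 TPM in VE (SD, n = 3), a log2 fold change of 4.23 (SE 0.28, adjusted p = 2.29e-04). The gain is 0.238% of its mean level in the brain libraries, and 15 of 33 other genes abundant in brain and nearly absent from liver were also higher in 3 of 3 VE libraries, where chance gives 5%. Fam84a, whose protein is also called LRATD1, rose from 0.352 ± 0.253 to 11.8 ± 5.11 TPM (3.20, SE 0.39, adjusted p = 0.0153), a call lost in 7 of 28 other settings, leaving out WT 3 or WT 4 among them. Gpr34 lies on chromosome X, bases 13632089 to 13640858, forward strand, and Fam84a on chromosome 12, bases 14146830 to 14152054, reverse strand (GRCm38). The difference in response between brain and liver passed for Gpr34 as well, by -4.44 (SE 0.42, adjusted p = 0.00625 for the interaction). In all 7 of 15123 genes passed, 3 higher and 4 lower, against 595 with an unadjusted p under 0.05. Leaving out 1 library gave 3 to 13. The 5 called genes besides Gpr34 and Fam84a have noncoding or predicted names or none.

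Several genes stood apart between the liver groups without passing. Cdkn2b, a cell cycle inhibitor, was at 5.87 ± 3.36 TPM in VE and 0.00798 ± 0.00757 in WT (log2 fold change 2.62, SE 0.40, adjusted p = 0.1005). Mmp9, a matrix-degrading protease, was at 109 ± 15.0 and 20.7 ± 4.47 TPM (2.35, SE 0.40), and Cd63, a tetraspanin of late endosomes, at 43.0 ± 24.1 and 10.5 ± 6.01. Cd68, a lysosomal glycoprotein of macrophages, was at 861 ± 202 and 1670 ± 106 TPM, Rad51b, a DNA repair gene, at 0.330 ± 0.467 and 6.53 ± 3.55, and the plasma protein gene Hrg at 0.964 ± 0.327 and 6.35 ± 2.26. Trem2, a lipid-sensing receptor, stood at 40.4 ± 11.1 and 23.1 ± 15.8 TPM. Braf was at 6.64 ± 1.45 TPM in VE and 2.54 ± 0.506 in WT (1.10, SE 0.72) and Csf1r at 350 ± 8.90 and 331 ± 32.8. Of 16 MAPK pathway target genes 0 passed, also when adjusted over the list alone; Etv5 was at 25.4 ± 1.82 and 14.7 ± 2.39 TPM and Ccnd1, cyclin D1, at 17.1 ± 1.64 and 9.14 ± 1.64.

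In limma's camera test 6 lists were lower in liver VE, none of which passed with an estimated correlation, where all 6 had an adjusted p = 0.359 with an estimated correlation. Of 24 lysosome genes 0 fell over all genes and 3 were lower when adjusted over the list alone (camera adjusted p = 1.29e-05); the lipase gene Lipa was at 97.3 ± 33.5 TPM in VE and 192 ± 34.3 in WT, and the ceramidase gene Asah1 at 293 ± 65.5 and 535 ± 26.1. All 11 MHC class II genes had negative fold changes and 0 passed, also when adjusted over the list alone (adjusted p = 0.00513), with H2-Aa at 2528 ± 619 and 4478 ± 914 TPM and Cd74, the invariant chain, at 5236 ± 517 and 9072 ± 2177. Of 22 cytokines and chemokines 0 passed and 2 were lower when adjusted over the list alone (adjusted p = 0.00894), with Ccl4 at 11.8 ± 9.41 and 77.7 ± 15.7 TPM and Il1a at 93.4 ± 42.8 and 229 ± 37.4. A split that mixed the genotypes, with WT 3, WT 5 and VE 5 in 1 group, gave this list an unadjusted camera p of 0.00159. The real split gave 0.00137. Of 18 complement genes 0 passed and 1 was lower when adjusted over the list alone (adjusted p = 0.0105), with the C1 inhibitor gene Serping1 at 2.01 ± 1.80 and 10.0 ± 4.10 TPM and the receptor gene C3ar1 at 50.4 ± 12.05 and 90.0 ± 12.02. Of 20 Kupffer cell genes 0 passed, also over the list alone (adjusted p = 0.0410), with Il18bp at 645 ± 42.0 and 1192 ± 42.7 TPM and Timd4 at 427 ± 83.5 and 657 ± 67.0.

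Hepatocyte markers moved with the same groups: 13 of 14 tested members had negative fold changes in VE and 0 passed, also over the list alone (camera adjusted p = 1.53e-04), with Alb at 185 ± 146 and 299 ± 94.5 TPM and Ahsg at 24.4 ± 19.9 and 54.8 ± 7.92. The adult haemoglobin gene Hbb-bs had 1947, 17.9 and 9.65 TPM in the VE libraries and 8.16, 17.5 and 6.65 in WT. Fitted without the brain groups, limma called 0 genes, with 1440 at an unadjusted p under 0.05, against 595 in the joint fit. With array weights 42 genes passed. The spread of the joint fit is likely too large for liver and too small for brain. The 7 liver calls and the 227 brain calls therefore do not compare the size of the response between organs. Without the haemoglobin-holding column of VE 3 Gpr34 no longer passed.

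**Figure D2:**
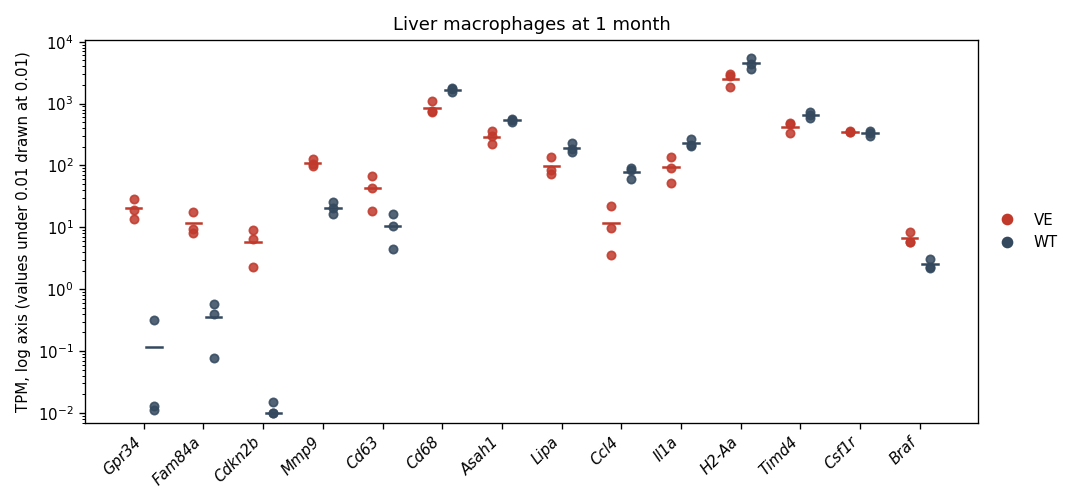
TPM of 14 genes (log axis) in liver macrophages at 1 month, with a point per sample, 3 VE and 3 WT, and bars at the group means. Gpr34 and Fam84a passed the test; the other 12 genes are drawn as values that did not pass.

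Whether the genotype difference itself differed between brain and liver was tested with the interaction, which called 50 genes, 11 with a larger and 39 with a smaller log2 fold change in brain. Larger and smaller here refer to the signed value, not to its size. Leaving out 1 library gave 2 to 196 calls, with 2 without liver WT 4 and, without brain WT 5, 89 larger and 107 smaller. Ifitm3 changed by 2.91 in brain (SE 0.37) and -0.08 in liver (SE 0.33), a difference of 2.996 (SE 0.49, adjusted p = 0.0382). Ier3 changed by 4.33 in brain and had -0.69 in liver, a difference of 5.01 (SE 0.76). For Pmm2, Zfand4 and Etfrf1 the difference was 5.08, 4.76 and 4.69. For Mobp the values were -5.19 and 0.05, a difference of -5.24 (SE 0.81), and for Haus4, Cdc45, Ogfod2 and Zfp78 the difference lay between -5.73 and -5.11. The interaction was lost in 14 of 26 other settings for Ifitm3 and for Mobp, in 16 for Ogfod2, in 13 for Ier3 and for Zfand4, in 12 for Etfrf1 and for Haus4, in 10 for Cdc45 and in 5 for Pmm2, and in 6 of 24 for Zfp78. The inflammatory cytokine list had 0 single members past the threshold but passed as a set, and 7 members were higher when adjusted over the list alone (camera adjusted p = 2.13e-08; adjusted p = 0.0132 with an estimated correlation).

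In brain macrophages at 6 months the comparison asked how the mutant cells stand at a later age. The apolipoprotein gene Apoc4 rose from 0.945 ± 1.34 TPM in WT (SD, n = 2) to 1029.97 ± 50.6 TPM in VE (SD, n = 2), a log2 fold change of 9.24 (SE 0.54, adjusted p = 0.00739). Its neighbours Apoc2, Apoc1 and Apoe, apolipoproteins that carry lipid, rose by 6.12 (SE 0.44), 5.10 (SE 0.92) and 3.13 (SE 0.53), with Apoe at 11446 ± 5236 TPM in VE and 1415 ± 966 in WT. The Apoe call was lost in 5 of 19 other settings, leaving out either VE library among them, and the Apoc1 call in 4, leaving out VE 1 among them, with log2 fold changes from 2.37 to 3.89 and from 3.79 to 6.42. Cx3cr1, the microglial receptor for fractalkine, fell from 372 ± 7.73 to 25.1 ± 4.21 TPM, by 3.84 on the log2 scale (SE 0.28, adjusted p = 0.00739), and Csf1r from 435 ± 20.98 to 71.9 ± 12.4 TPM (-2.59, SE 0.25). Over all 12174 genes the median log2 fold change was -0.73, so a change can be read against that shift: relative to it Apoc4 stood at 9.97, Apoe at 3.85, Cx3cr1 at -3.12 and Csf1r at -1.86. The 4 apolipoprotein genes lie on the reverse strand of chromosome 7, between base 19671579, the start of Apoc2, and base 19699188, the end of Apoe (GRCm38).

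Of the 22 homeostatic microglia genes 19 fell, 0 rose and 3 did not pass, and all 22 were lower when adjusted over the list alone. Selplg, the ligand of P-selectin, fell from 946 ± 3.61 to 68.9 ± 9.53 TPM, Siglech from 1653 ± 244 to 245 ± 12.8 and Sparc, a matrix glycoprotein, from 886 ± 1.71 to 68.5 ± 24.8. Crybb1, a crystallin gene of microglia, fell from 105 ± 44.3 to 2.39 ± 2.23 TPM. The median of the list was -2.58, or -1.86 relative to the shift (camera adjusted p = 2.74e-10; adjusted p = 0.507 with an estimated correlation). With quantile normalization 13 of the 22 fell, with a median of -2.11, and with the length trend removed 10, with a median of -1.66.

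Of 27 neurodegeneration-associated microglia genes 14 rose, 3 fell and 10 did not pass, and 19 were higher and 5 lower when adjusted over the list alone. Spp1 rose from 2052 ± 1866 to 24916 ± 5148 TPM, Igf1, a growth factor, from 3.67 ± 1.75 to 112 ± 0.907, Clec7a, a receptor for fungal glucans, from 174 ± 74.6 to 1199 ± 289, Ch25h from 55.2 ± 13.8 to 517 ± 107 and Cd52 from 1671 ± 312 to 8452 ± 1603. The Spp1 call was lost in 5 of 19 other settings, leaving out either VE library among them (log2 fold changes 2.87 to 5.07). Those of Igf1 and Clec7a were lost in 4 each, leaving out VE 2 among them. The list's median was 1.74, or 2.46 relative to the shift (adjusted p = 7.15e-11; adjusted p = 0.507 with an estimated correlation). Of 15 lipid efflux and storage genes 4 rose and 0 fell, with 5 higher when adjusted over the list alone (adjusted p = 5.69e-05; adjusted p = 0.507 with an estimated correlation). Of 20 inflammatory cytokines and chemokines 5 rose and 3 fell, with 6 higher and 4 lower when adjusted over the list alone (adjusted p = 0.00430; adjusted p = 0.526 with an estimated correlation). Il1rn, the interleukin-1 receptor antagonist, rose from 4.46 ± 3.01 to 176 ± 43.0 TPM, the neutrophil chemokine Cxcl1 from 0.00927 ± 0.0131 to 41.9 ± 41.4 and Ccl12 from 1079.7 ± 638 to 8318 ± 4882. The Ccl12 call was lost in 6 of 19 other settings, leaving out either VE library among them (2.30 to 3.59). That of Il1rn was lost in 4, leaving out VE 2 among them. Of the cytokine list 3 rose and 2 fell with quantile normalization, and 6 rose and 0 fell with the length trend removed.

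Of 24 lysosome genes 14 fell and 1 rose, with 19 lower and 2 higher when adjusted over the list alone (camera adjusted p = 0.00259; adjusted p = 0.668 with an estimated correlation). Lamp1, a lysosomal membrane protein, fell from 575 ± 44.5 to 92.4 ± 8.23 TPM and Psap, a precursor of sphingolipid activators, from 141 ± 5.14 to 17.3 ± 1.01. The list's median was -1.54, or -0.82 relative to the shift. With quantile normalization 9 fell and 1 rose (median -1.12). With the length trend removed 6 fell and 4 rose (median -0.59). Of 17 immediate early genes 6 fell and 0 rose, with 11 lower when adjusted over the list alone (adjusted p = 0.00820; adjusted p = 0.654 with an estimated correlation). With quantile normalization 3 of the 17 fell and with the length trend removed 1, with medians of -0.74 and -0.77 against -1.68. Of 12 MAPK pathway target genes Ier3, Fos, Egr1 and Etv5 fell, by 3.37, 2.30, 2.33 and 2.07 on the log2 scale, and 8 were lower when adjusted over the list alone, but the list did not pass in camera (adjusted p = 0.158). With quantile normalization none of these 4 genes passed. The calls of Fos, Egr1 and Etv5 were lost in 7, 10 and 9 of 19 other settings, leaving out either VE library among them. Braf was at 0.851 ± 0.412 TPM in VE and 5.77 ± 0.709 in WT (-1.89, SE 0.55, adjusted p = 0.0588), or -1.16 relative to the shift.

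In camera, which sets a list against the other genes, the type I interferon list was also higher (adjusted p = 0.0123, or 0.668 with an estimated correlation). Zbp1 passed among 20 members, and 0 did when adjusted over the list alone. Its median was 0.38, or 1.11 relative to the shift, and the directional fry test gave an adjusted p = 0.786. The Kupffer cell list was higher in camera too (adjusted p = 0.0327, or 0.526 with an estimated correlation). In it 2 of 9 members rose and 1 fell, as they did when adjusted over the list alone. Its median was 0.97, or 1.69 relative to the shift, and directional fry gave an adjusted p = 0.241. Of 18 matrix remodelling and growth factor genes 4 rose and 2 fell, with 4 higher and 4 lower when adjusted over the list alone; the test was upward (adjusted p = 0.0327; adjusted p = 0.573 with an estimated correlation) and the mean 0.67, while the median was -0.0042, or 0.60 with quantile normalization and 0.91 with the length trend removed.

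Other macrophage genes that rose were Cxcl13, a B cell chemokine, from 17.1 ± 24.1 to 2813 ± 3016 TPM, Ms4a7, a membrane gene on the list of border-associated macrophages, from 20.99 ± 18.1 to 1599 ± 1640 and Dcstamp, which takes part in cell fusion, from 0.00680 ± 0.00962 to 47.3 ± 2.95. Clec4d, a C-type lectin, rose from 0.00978 ± 0.0138 to 71.4 ± 69.4 TPM, Fn1, fibronectin, from 0.802 ± 0.155 to 45.01 ± 28.6, Cdkn2b from 0.117 ± 0.166 to 5.80 ± 3.69 and Zbp1, a sensor of nucleic acids, from 4.39 ± 3.77 to 77.9 ± 68.7. The calls of Cxcl13 and Zbp1 were each lost in 7 of 19 other settings, leaving out either VE library among them, and that of Cdkn2b in 7 of 16. Their log2 fold changes ranged from 5.71 to 10.82, from 2.70 to 4.77 and from 1.03 to 4.85. The Ms4a7 call was lost in 4 of 19, leaving out VE 1 among them. Ifitm3 did not pass, at 3028 ± 2941 and 359 ± 314 TPM. Ecscr, a surface gene named for endothelial cells, fell from 261 ± 51.8 to 4.73 ± 6.54. It was also abundant in the brain macrophage libraries at 1 month, with a mean of 436 TPM, so its fall is not read as endothelial. The complement gene C1qa fell from 2154 ± 273 to 709 ± 199 and the integrin gene Itgam from 127 ± 5.76 to 27.2 ± 2.90. Ly6c2, a marker of monocytes, fell from 58.7 ± 39.8 to 0.5003 ± 0.227 and Cd74 from 679 ± 151 to 328 ± 80.0, although Cd74 lay at -0.32 relative to the shift and its call was lost in 11 of 19 other settings and that of Ly6c2 in 6 of 17. The calls of C1qa and Itgam were lost in 6 and 5 of 19, leaving out VE 2 among them. B2m, the light chain of MHC class I, stood at 26468 ± 233 and 15883 ± 208 TPM and passed as higher, but not with quantile normalization, where its fold change was 0.

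Markers of other cells differed in direction. Mbp fell from 21.5 ± 8.15 to 4.19 ± 0.476 TPM, a call lost in 11 of 19 other settings, among them quantile normalization, removal of the length trend and leaving out WT 1, VE 1 or VE 2, with log2 fold changes from -2.94 to -1.11. The oligodendrocyte list summed to 11.7 and 13.9 TPM in VE and 66.2 and 40.0 in WT. The endothelial list summed to 9.54 and 19.3 TPM in VE and 6.28 and 8.29 in WT. S100a8, an abundant gene of neutrophils, had 5.99 and 11.1 TPM in VE and 0.158 and 2488 in WT. The libraries themselves differed with genotype: genes above 0 TPM numbered 30001 to 33377 in the VE columns and 21320 to 23630 in the WT columns. The predicted gene Gm10800 had 7691 to 46158 and 179 to 329 TPM. Fold changes went down with transcript length (Spearman correlation across genes -0.266). In all, 2224 genes passed, 440 higher and 1784 lower, while quantile normalization gave 518 higher and 417 lower and removing the trend with transcript length 610 higher and 403 lower. Without VE 2 the count was 231, without VE 1 it was 594, and with a sex term, which separates the only male library, VE 2, limma called 0 genes, with 3145 at an unadjusted p under 0.05 against 5010 without that term.

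**Figure D3:**
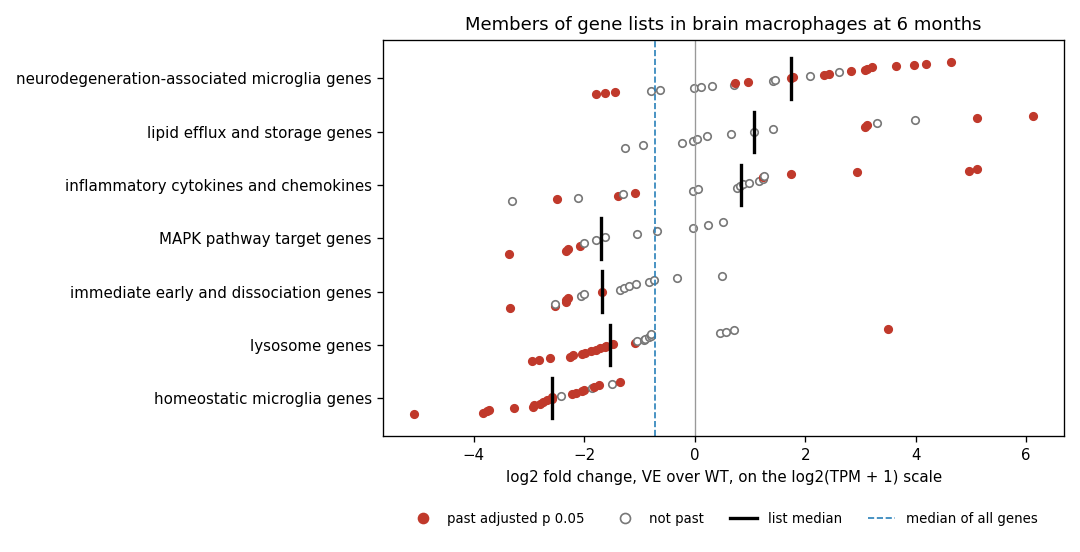
Log2 fold changes (VE over WT, log2(TPM + 1) scale, 2 samples per group) of the tested members of 7 gene lists in brain macrophages at 6 months; filled points passed adjusted p 0.05 in limma, black bars are list medians and the dashed line is the median of all genes, -0.73. The homeostatic list has its median at -2.58 with 19 of 22 members past the threshold, and the neurodegeneration-associated list at 1.74.

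The last comparison asked whether the same genes changed at both ages and in both organs. Across the 11482 genes tested at both ages, fold changes in brain had a Spearman correlation of 0.0505 across genes, which are not independent replicates. Of the 65 higher genes at 1 month and the 352 at 6 months, 6 were shared, against 1.99 for independent lists (Fisher's exact test, 2-sided p = 0.0144), among them Ccl12, Cd52, Zfand4 and Nop10. Leaving out 1 library gave 1 to 12 shared higher genes, with 1 without the 6-month VE 2 and 2 without VE 1. The value for independent lists was not recomputed for these shorter lists. Of the 116 and 1763 lower genes 13 were shared, against 17.8 for independent lists (p = 0.245, Fisher's exact test), with 0 to 33 when 1 library was left out, while 11 genes were higher at 1 month and lower at 6 months and 4 the reverse. Ier3 rose at 1 month and fell at 6 months, at 113 and 77.6 TPM in the older WT libraries, and Fabp5 fell at 1 month and rose at 6 months. Between brain and liver at 1 month the correlation over 15123 genes was 0.0208, with 0 higher and 1 lower gene shared.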

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

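The tests on Gpr34, on the homeostatic microglia list and on the brain calls at 1 month were chosen after those results were seen. The interaction and the counts of calls for the liver splits were planned, but how to read the liver splits was written later. Splits of the brain libraries were not in the plan. For the cytokine list, how to read them was written before that result was seen.

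The genotype difference differed between brain and liver at 1 month, by limma's interaction term, for 11 genes with a higher and 39 with a lower signed value in brain. The brain minus liver difference on the log2 scale was 5.08 for Pmm2, 5.01 for Ier3, 4.76 for Zfand4, 4.69 for Etfrf1 and 2.996 for Ifitm3. It was -5.73 for Haus4, -5.53 for Cdc45, -5.42 for Ogfod2, -5.24 for Mobp and -5.11 for Zfp78. These last genes had log2 fold changes of -5.19 to -4.42 in brain and 0.05 to 1.11 in liver, so their change was larger in size in brain. With array weights limma called 0 of these interactions, with 995 genes at an unadjusted p under 0.05, and leaving out 1 library gave 2 to 196.

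Gpr34 was higher in liver VE, and a rise of this gene alone in liver macrophages is argued against by 15 of 33 other brain-abundant genes that were also higher in every VE library, with 0 lower in every one and 5% given by chance. Brain macrophage RNA or reads in the liver VE libraries are a candidate explanation: the median gain of those genes was 0.296% of their brain level, against 0.238% for Gpr34. In 5 of 6 VE columns the ratio of Gpr34 to Fcrls was 21.4 to 23.7, against 19.6 in brain, and the columns of VE 3 held 0.411 and 27.2 TPM of Gpr34. Against it, but weakly, P2ry12 stood at 101 ± 44.1 TPM in VE and 118 ± 6.96 in WT (SD, n = 3 each), where the Gpr34 gain would give 160.2, and Tmem119 at 1.51 ± 0.702 and 2.28 ± 2.26. The spread of P2ry12 in VE and of Tmem119 in WT is about the size of the gain looked for, so neither decides. The VE 3 column with 0.411 TPM of Gpr34 held 0 TPM of Fcrls, 0.0245 of Serpine2 and 0.0481 of Tmem119. The column with 27.2 TPM held 1.22, 2.06 and 2.02. Whether a few brain-like cells lived in the liver or material was carried over during sorting or sequencing was not tested.

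At 6 months the homeostatic microglia list was lower in VE, and its upper quartile stayed at -1.53 with quantile normalization and at -1.05 with the length trend removed, so neither a shift of the whole scale nor a loss of long transcripts accounts for the list as a whole. Of its 22 members 13 and 10 passed under these settings, against 19 before. Dilution by other cells would need 75.2% of the VE RNA for the fall of 2.01 at that quartile on the deposited scale, yet VE marker sums, over the highest sum of any brain library in the separate tables of both ages, allow at most 14.1% for neurons, 13.4% for astrocytes, 2.90% for oligodendrocytes, 69.0% for endothelium, 0.685% for neutrophils and 13.3% for lymphocytes. This argues against each of these types alone if levels can be compared across the tables. The margin was least for endothelium, and for neutrophils it rested on 1 repeat column of WT 2. The reference sums of neurons, astrocytes, oligodendrocytes and endothelium were from 1-month libraries. Within 6 months, endothelial sums were higher in VE (9.54 and 19.3 TPM) than in WT (6.28 and 8.29). Neuron sums overlapped, and those of astrocytes and oligodendrocytes were lower in VE. Mixtures of these types were not tested. A change of state of the mutant microglia, as the design would have it, may account for the pattern, as may other macrophages passing the sort. Sex, handling, a sort gate that may differ with genotype and 2 samples per group leave both open. So does a difference between the libraries that followed genotype. The predicted gene Gm10800 had 7691 to 46158 TPM in the 4 VE columns and 179 to 329 in the 3 WT columns. Genes above 0 TPM numbered 30001 to 33377 and 21320 to 23630. Whether this difference accounts for part of the pattern was not tested.

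The calls between VE and WT brain at 1 month numbered 227, and other splits of the 5 libraries gave 121 to 202. The 202 came from a split that kept both WT libraries together with VE 3, and so kept part of the genotype contrast. Splits that separated the WT libraries gave 121 to 153. Uneven detection between libraries made from little RNA may account for much of the 227 calls, as may a joint-fit spread too small for brain. The splits cannot tell these apart. Myelin RNA in the WT libraries stays open: 1 of the 155 lower calls is an oligodendrocyte list member, but with 5 members tested that count could not exclude it. For the inflammatory cytokine list the real split gave a camera p of 1.63e-06 and the lowest of the others 1.22e-04, so 1 of 10 splits, the real one, gave a p as low. The split with 1.22e-04 also kept both WT libraries together, with VE 5. Splits that separated the WT libraries gave a camera p of 0.0852 to 0.776. With 10 splits no share under 0.05 can be reached.

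For liver at 1 month 1 of 10 splits, the real one, called as many genes, with 7 calls and 4 as the highest of the others. The splits are too few for a share under 0.05.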

How the results depend on the processing

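Settings on repeat columns, sex, transcript length and doubted columns were chosen after the data were seen, and the cause of a change was not tested except where fewer samples were used. The TPM tables give no depth.

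Calls between VE and WT brain at 1 month were 149 with no filter, 22 with array weights and 0 when fitted without liver. In liver they were 3 with a pseudocount of 5, 28 with no filter, 42 with array weights and 0 without brain. At 6 months they were 23 with no filter, 935 with quantile normalization, 1363 with no trend, 4 with first repeat columns, 3955 with each repeat column as a library, 1013 with the length trend removed and 0 with a sex term. Brain against liver gave 2012 with array weights and 1962 with first repeat columns. The interaction gave 4 with no filter, 2 with a filter of 5 TPM, 29 with quantile normalization, 0 with array weights, 23 with repeat columns averaged on the log2 scale and 21 with each as a library.

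Same-number correlations of deviations from group means were 0.0042 and -0.016 in brain at 1 month, 0.039, -0.018 and 0.017 in liver and 0.0079 at 6 months. In liver they lay within the range of unlike numbers, -0.058 to 0.043. In brain a group of 2 samples has mirrored deviations, so these values cannot tell whether replicate numbers pair the samples. Fits with a replicate block used the compared groups alone and, in brain at 1 month, only samples whose number occurs in both genotypes. In them limma called 0 genes in brain (507 at an unadjusted p under 0.05), 0 in liver (1272) and 2844 at 6 months. Without a block, fits of the compared groups alone also called 0 genes in brain (830) and 0 in liver (1440). The loss of calls at 1 month therefore cannot be credited to the block.

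Leaving out 1 library gave 130 to 484 calls in brain at 1 month, with 130 to 144 without a liver library and 426 to 484 without a brain library, 3 to 13 in liver, 231 to 2299 at 6 months, 2232 to 3614 for brain against liver and 2 to 196 for the interaction. A group left with 1 sample is there assumed to vary like the others. List counts then ranged from 3 to 6, 3 to 8, 7 to 10, 15 to 17 and 3 to 5. With an estimated correlation camera called 0 lists in brain at 1 month, 0 in liver, 0 at 6 months, 9 for brain against liver and 1 for the interaction. The directional fry test called 0 in liver and 0 at 6 months, and the mixed test 13 in brain at 1 month, 24 for brain against liver, 11 for the interaction and 16 at 6 months.

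The correlation between ages was 0.0680 with a pseudocount of 5 and 0.0364 with quantile normalization, and 0.0273 to 0.0813 leaving out 1 library; that between organs was -0.0039 to 0.0347. Lower genes shared between ages were 2 with quantile normalization and 0 to 33 leaving out 1 library, higher ones 1 to 12. Lower genes shared between organs were 0 with a pseudocount of 5 or log2 averages and 0 to 1 leaving out 1 library. S100a8 at 6 months turned to 2.99 without WT 2 and 2.76 without its S100a8-rich column, with -8.08 to 2.99 leaving out 1 library. The mitochondrially encoded list turned at 6 months with quantile normalization (adjusted p = 0.0167) and without VE 2 (0.0443), and in the interaction without brain WT 5 (0.0222); leaving out 1 library its adjusted p was 7.83e-05 to 0.902 at 6 months and 1.45e-04 to 0.993 in the interaction. For the called genes named in the text, 422 of 525 values in brain at 1 month stayed past the threshold. In liver 45 of 56 stayed and at 6 months 551 of 728. For the interaction 143 of 258 stayed and for brain against liver 270 of 270. These values cover 19 of the 227 calls in brain at 1 month and 39 of the 2224 at 6 months. Most of these genes were picked for large changes or low p, so the shares may be too high for all calls.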

Other observations

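No test in this part was chosen after its result was seen, and all compare brain with liver macrophages in WT at 1 month or give values. Of 18 lipid efflux and storage genes 10 were lower and 2 higher in brain, with 11 lower and 3 higher when adjusted over the list alone (camera adjusted p = 2.10e-05; adjusted p = 0.0157 with an estimated correlation). Of 22 inflammatory cytokines and chemokines 10 were lower and 1 higher, with 12 lower and 3 higher when adjusted over the list alone (adjusted p = 7.33e-04; adjusted p = 0.0282 with an estimated correlation). Of 13 MHC class I presentation genes 7 were lower and 0 higher, with 8 lower when adjusted over the list alone (adjusted p = 1.50e-04; adjusted p = 0.0157 with an estimated correlation). Of 32 cell cycle genes 8 were lower and 1 higher, with 9 lower and 1 higher when adjusted over the list alone (adjusted p = 5.29e-06; adjusted p = 0.0674 with an estimated correlation).

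Markers of neutrophils summed to 5167 TPM in the 6-month sample WT 2 and to 46.5 in WT 1, 23.1 in VE 1 and 35.4 in VE 2; the sum of WT 2 was carried by 1 of its 2 repeat columns, with S100a8 at 4976 TPM there and 0.594 TPM in the other. Markers of lymphocytes summed to 214 TPM in WT 2 and to 25.5, 25.4 and 28.5 in the other libraries. The B cell gene Cd79a had 98.8 and 101 TPM in the 2 columns of WT 2. An F4/80 gate selects macrophages, yet RNA of these markers was in that library.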
